A study of Mus musculus with 18 samples.

How the data were processed

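RNA sequencing was done on 18 samples of cells sorted from the trachea of untreated mice. Per the labels, all mice carried a BAC transgene that places eGFP under the control of the choline acetyltransferase (Chat) locus, so that brush cells fluoresce. Per the labels' protocols, tracheas were digested with dispase and then papain, dead cells were excluded with propidium iodide, and cells were sorted into a lysis buffer. Brush cells (7 samples) were CD45 negative, EpCAM positive and eGFP positive, EpCAM+ cells (7 samples) were CD45 negative and EpCAM positive, and CD45+ hematopoietic cells formed 4 samples. The EpCAM+ gate as the labels word it does not exclude eGFP+ cells. Nothing in the labels says whether the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical in part. Y-linked genes were counted in some libraries of each group and hardly or not in others, so no group came from 1 animal alone. How many animals each group holds is not known.

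Several kinds of values were deposited. The main one is a table of whole-number read counts for 26327 gene symbols in all 18 samples, which the authors deposited unnormalized. Per the file headers, each sample also has an RSEM table with expected counts (estimated counts that need not be whole) and TPM for 47729 gene identifiers, of which 47224 were given a symbol from the annotation. A further deposited table holds a normalized signal, and dividing the deposited counts by 1 size factor per library gave the same values to within a relative deviation of 5.1e-15. Per the submitters' processing notes, the tools were STAR 2.4.2a, Picard, RSEM 1.2.21, featureCounts and DESeq2 and the build was mm10, with no role or order given. The gene annotation the authors counted on and the strand setting are not given in the sources used here. Coordinates and transcript lengths therefore come from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, and 24712 symbols were shared between the count table and the RSEM tables.

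Genes of multigene families and overlapping genes are uncertain, because how reads shared between copies were assigned is not given. This applies to lysozymes, keratins, bitter taste receptors, protocadherins, chitinase-like proteins, granzymes, MHC genes and heat shock genes, and to antisense pairs such as Xist and Tsix. The lowest chi-square per degree of freedom between libraries of 1 group was 6.3, more than sampling noise, so no library was taken for a copy of another and all 18 were kept. That comparison does not show whether they came from separate animals or preparations. The table includes 5 ribosomal RNA genes, which stayed in the main calculation and were left out in an alternative.

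Sample groups were taken from the labels before the data were examined, as were the tests, the gene lists, the rule for named genes and the alternatives, except those named as later choices. Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the filterByExpr filter by group, which left 13418 genes and removed 12909. All 18 libraries entered 1 fit with group as the only term, so the 3 groups shared 1 estimate of spread per gene. The 3 contrasts were brush against EpCAM+, brush against CD45+, and EpCAM+ against CD45+ as the reference comparison. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. The brush signature was defined as genes with an adjusted p below 0.05 and a log2 fold change of at least 1 in both brush contrasts. Levels are CPM, counts scaled to the TMM library size, as mean ± SD over the libraries of a group.

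Gene lists numbered 30 and covered brush cell markers, taste transduction, eicosanoid synthesis and receptors, cholinergic genes, purinergic receptors, epithelial cytokines, type 2 cytokine receptors and targets, other epithelial cell types, leukocyte classes and other cell types the gates could hold, and proliferation, stress, Notch, red blood cell, mitochondrial, immune receptor signalling and sex-linked genes. They were written from general knowledge of these cells, which may include work published from these samples, so the direction of the brush marker list is not independent evidence. Lists share some members: brush markers and taste transduction share 5 genes, brush markers and immune receptor signalling 4, and pan-leukocyte genes and immune receptor signalling 4. List members were counted past the adjusted p over all genes, and again after adjustment over the list alone. Each list was tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, and with fry, which asks whether a list's genes move one way without comparing them with other genes. Camera p-values were adjusted over the 30 lists of a comparison. List p-values given without a named correlation are those at the preset one. At the estimated correlation they could be much larger, such as adjusted p = 0.0399 against 5.5e-12 for B cell genes in brush against CD45+ cells. The median log2 fold change and the camera direction differed in sign in brush against EpCAM+ for the type 2 list and the MHC class II list, and camera and fry differed in direction for the macrophage and dendritic cell list, none of which passed the camera test.

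Genes are named by this rule: 23 genes fixed in advance; the 10 genes with the largest log2 fold change in each direction for the brush contrasts and the 5 for EpCAM+ against CD45+, with at least 50 CPM in the higher group and no overlap between the groups; the 20 signature genes with the largest value of the smaller of their 2 log2 fold changes; for each list the 2 to 4 members with the largest changes and the largest opposite change; and the members of lists with 5 or fewer past the test. Immunoglobulin and T cell receptor segments and predicted genes were skipped in the rankings. CPM levels are given for the 23 fixed genes and other genes are given by fold changes. Some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen, which is said where they appear.

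Where 1 group had no counts of a gene, the fold is a lower bound set by 3 counts over that group, which corresponds to 0.101 CPM in brush, 0.0986 CPM in EpCAM+ and 0.172 CPM in CD45+ cells. Where it had 1 to 3 counts, the ratio is given with an exact 95% counting interval. These bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

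The tests were run on simulated counts with known changes, drawn from the means, library sizes and dispersions of these libraries. In brush against EpCAM+ (13133 genes), 9 of 100 genes changed 2-fold and 71 of 100 changed 4-fold were recovered, with 6 false calls. In brush against CD45+ (12990 genes), 1 of 100 and 31 of 100 were recovered with 0 false calls, and in EpCAM+ against CD45+ (12997 genes), 6 of 100 and 60 of 100 with 0. A planted list of changed genes passed the camera test in each of the 3 comparisons and 0 of the other lists did. Correlation between the genes of a list was not part of what was drawn. In the real lists its estimate ranged from -0.106 (endothelial genes) to 0.723 (red blood cell genes) in brush against EpCAM+ cells. The simulation therefore cannot show whether list p-values at the preset correlation hold for lists of correlated genes. For the overlap of the brush contrasts, which share their brush libraries, 20 simulations of unchanged groups were run and the brush libraries were also split between the contrasts.

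Alternatives were RLE and upper-quartile scaling, no filter on low counts, a minimum of 10 CPM in at least 1 group, DESeq2 1.42.0, limma voom with sample quality weights, RSEM expected counts rounded to whole numbers, fits of only the 2 groups compared, a test against a 2-fold change (glmTreat), an adjusted p below 0.01, the replicate number as a block, and leaving out each of the 18 libraries in turn. For the similarity of libraries, log2(TPM + 1) and the 500 most variable genes were the alternatives. Chosen after the data were seen were leaving out the ribosomal RNA genes and leaving out the 3 libraries that stood apart from their groups.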

Results

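Brush cells, also called tuft cells, are rare chemosensory cells of the airway lining. Their RNA was compared with that of the EpCAM+ cells and the CD45+ hematopoietic cells sorted from the same organ, the trachea of untreated mice. The 18 libraries comprised 7 of brush cells, 7 of EpCAM+ cells and 4 of CD45+ cells. Library totals ranged from 838328 to 6031711 counts in brush cells, from 2442601 to 6087184 in EpCAM+ cells and from 371652 to 7438791 in CD45+ cells. Ribosomal RNA genes took 24.0 to 63.49% of the counts in brush libraries, 12.21 to 34.11% in EpCAM+ libraries and 20.72 to 43.38% in CD45+ libraries. Between 11814 and 15725 genes were detected per brush library, 14478 to 15841 per EpCAM+ library and 10317 to 16196 per CD45+ library.

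The sorted populations separated in the principal components of log2 CPM. CD45+ libraries lay at 190.8 to 229.9 on the first component (42.7% of the variance), and the second (29% of the variance) held brush libraries at 88.2 to 100.2 and EpCAM+ libraries at -120.6 to -101.3. For each of the 18 libraries the closest library was one of its own group. The median Spearman correlation across genes, which are not independent replicates, was 0.931 between brush libraries, 0.911 between EpCAM+ libraries and 0.848 between CD45+ libraries, against 0.688 between brush and EpCAM+ libraries. In each group 1 library stood apart: brush replicate 4, EpCAM+ replicate 5 and CD45+ replicate 1 had median correlations with their own group of 0.849, 0.81 and 0.759, and all other libraries lay at 0.895 to 0.951.

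**Figure D1:**
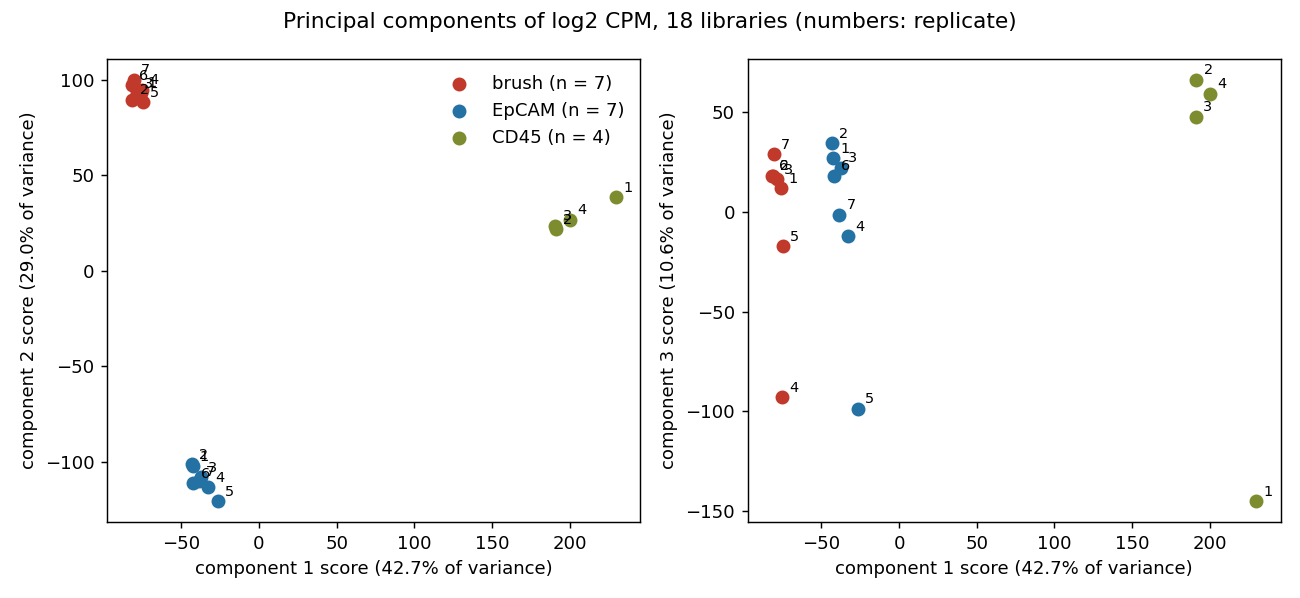
Each point is 1 library, placed by its scores on principal components of log2 CPM over 13418 genes (scores in log2 units) and coloured by sorted population. CD45+ libraries (n = 4) lie at 190.8 or above on the first component, brush (n = 7) and EpCAM+ libraries (n = 7) separate on the second, and brush 4, EpCAM+ 5 and CD45+ 1 lie at -92.8, -98.7 and -144.9 on the third.

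The first comparison asked which genes set brush cells apart from the tracheal epithelium at large. Brush cells were rich in transcripts of chemosensory cells. Trpm5, the cation channel that ends taste transduction, averaged 2330 ± 520 CPM in brush cells against 1.04 ± 1.10 CPM in EpCAM+ cells (SD, n = 7 each), a log2 fold change of 11.09 ± 0.68 (SE, adjusted p = 2.94e-11). Gnat3, the taste G protein alpha subunit gustducin, averaged 3350 ± 1270 against 1.59 ± 1.65 CPM (log2 fold change 11.04 ± 0.91). Il25, which encodes the cytokine IL-25, averaged 213 ± 119 CPM in brush cells and had 0 counts in EpCAM+ cells, at least 1620-fold higher. Pou2f3, the transcription factor that tuft cells require, averaged 193 ± 37.1 against 1.92 ± 1.47 CPM (6.73 ± 0.52).

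Other fixed brush genes were likewise higher. Dclk1, a kinase used to mark tuft cells, averaged 1740 ± 226 CPM in brush cells and 6.43 ± 4.96 CPM in EpCAM+ cells (log2 fold change 8.10 ± 0.51), and Avil, which encodes the actin-binding protein advillin, 1330 ± 457 and 2.91 ± 1.54 CPM (8.85 ± 0.45). Gfi1b, a transcription factor, averaged 14.4 ± 5.51 CPM in brush cells and was at least 137-fold higher than in EpCAM+ cells, which had 0 counts. Il17rb, a subunit of the IL-25 receptor, averaged 135 ± 20.5 against 0.745 ± 0.55 CPM (7.46 ± 0.54). Chat, the enzyme of acetylcholine synthesis, averaged 243 ± 72.6 against 1.28 ± 1.34 CPM (7.54 ± 0.64), and Epcam averaged 2130 ± 334 against 504 ± 143 CPM (2.08 ± 0.27). Chat drives the reporter used to sort brush cells and EpCAM was part of both gates, so these genes are checks of the sort. All 30 brush cell markers were higher in brush cells (30 adjusted over the list alone, camera adjusted p = 3.02e-32). That list came from general knowledge, which may include work published from these samples, so its direction is not independent evidence.

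Among all genes with at least 50 CPM and no overlap between the groups, the largest increases included receptors and signalling components. Pcdh20, a protocadherin, Cd300lf, an immune receptor, and Sucnr1, the succinate receptor, had 0 counts in EpCAM+ cells and were at least 4050-fold, 3060-fold and 2040-fold higher in brush cells. St6gal2, a sialyltransferase, the bitter taste receptor Tas2r138 and Cpvl, a carboxypeptidase, were at least 1120-fold, 957-fold and 718-fold higher. Gnb3, the G protein beta subunit of taste cells, rose by a log2 fold change of 12.57 ± 0.88 and Sh2d6, an SH2 domain adaptor, by 11.90 ± 0.60. Of 18 taste transduction genes tested, 17 were higher in brush cells (17 adjusted over the list alone, camera adjusted p = 2.73e-16), and Trpm4, a channel related to Trpm5, did not pass the test (-0.38 ± 0.37, adjusted p = 0.443). Among all genes, each of the 13 bitter taste receptors tested passed the filter on low counts only through brush libraries. The taste list holds such receptors, so its count and p were set in part by the filter.

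Genes of the other airway epithelial cells were lower in brush cells. Krt5, a keratin of basal cells, averaged 17.0 ± 13.1 CPM in brush cells against 931 ± 304 CPM in EpCAM+ cells (log2 fold change -5.82 ± 0.61). Scgb1a1, the club cell secretory protein, averaged 57.3 ± 57.7 against 5150 ± 5810 CPM (-6.54 ± 0.76), and Foxj1, the transcription factor of ciliated cells, 0.255 ± 0.355 against 5.27 ± 1.94 CPM (-3.86 ± 0.66). Single libraries carried some of these means: that of Scgb1a1 was 36.7 CPM without brush replicate 4 and 3030 CPM without EpCAM+ replicate 5, and the brush mean of Foxj1 was 0.148 CPM without replicate 1. Among genes with at least 50 CPM in EpCAM+ cells and no overlap between the groups, the largest decreases were of Spink5, a protease inhibitor, with 0 counts in brush cells and at least 459-fold more in EpCAM+ cells, and of Tff2, a trefoil peptide, with an EpCAM+ to brush ratio of 593 (counting interval 203 to 2880). They also included the keratins Krt13 (-8.75 ± 0.93), Krt75 (-7.53 ± 0.67) and Krt4 (-7.34 ± 0.95), lysozyme Lyz1 (-8.95 ± 1.41), surfactant protein Sftpa1 (-8.37 ± 0.93), haptoglobin Hp (-8.25 ± 0.74), and the matrix genes Fbln1 (-6.93 ± 0.66) and Abi3bp (-6.88 ± 0.57).

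Counted by list, 18 of 19 basal cell genes (18 adjusted over the list alone, camera adjusted p = 7.75e-14) and 17 of 18 club and goblet cell genes (17 over the list alone, adjusted p = 4.08e-12) were lower in brush cells. Basal genes with large changes were Snai2, a transcription factor (-7.29 ± 0.70), Dlk2 (-6.48 ± 0.82), Krt17 (-6.41 ± 0.84) and Trp63, the master regulator of basal cells (-6.35 ± 0.48). Among club and goblet genes Gp2 had an EpCAM+ to brush ratio of 1520 (272 to 60000), with 0 CPM in EpCAM+ replicate 3, and Spdef, a transcription factor of goblet cells, went the other way (3.30 ± 0.32). Ciliated cell genes were lower for 18 of 23 members and higher for 1 (19 lower and 1 higher over the list alone, adjusted p = 2.97e-05, but adjusted p = 0.163 with an estimated correlation). Rfx3, a transcription factor of ciliogenesis, was the higher one (2.21 ± 0.35), and Ccdc153 (-4.68 ± 0.72) and Dynlrb2 (-4.30 ± 0.64) were among the lower. A minimum of 10 CPM left 6 ciliated genes lower, and the fit of only these 2 groups, which tests fewer genes, left 10. All 6 ionocyte genes tested were lower (6 over the list alone, adjusted p = 0.000522), including Ascl3, a transcription factor, with at least 60.3-fold more in EpCAM+ cells, and the proton pump subunit Atp6v1b1 (-4.83 ± 0.58). With only these 2 groups fitted, 2 ionocyte genes were lower. Of 11 listed ionocyte genes, Foxi1 and Cftr, named after their values were seen, had too few counts for the test (50 each in EpCAM+ cells). Of the 6 tested, 2 were higher in CD45+ than in EpCAM+ cells, among them Atp6v0d2 (570 against 32 counts), so these were not particular to epithelial cells. Among neuroendocrine genes 5 of 12 were higher and 2 lower (6 and 2 over the list alone, adjusted p = 0.61). The secretory granule genes Resp18 (3.53 ± 1.06), Calca (3.46 ± 1.00) and Scg5 (3.21 ± 0.51) were higher and Chga was lower (-5.70 ± 1.19). With voom the calls of Resp18 (1.81, adjusted p = 0.196), Calca (1.63, adjusted p = 0.542) and Chga (-2.78, adjusted p = 0.0748) were lost. Without brush replicate 4 or EpCAM+ replicate 3, with voom, with a minimum of 10 CPM or with only these 2 groups fitted, 3 neuroendocrine genes were higher. Pan-epithelial genes were split, with 7 higher and 4 lower of 20 (7 and 4 over the list alone, adjusted p = 0.589): Krt18 was higher (2.08 ± 0.36) and Cdh3 lower (-6.32 ± 0.62).

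Genes of cell division, Notch signalling and the early stress response were also lower in brush cells. Of 14 proliferation genes 13 were lower (13 over the list alone, adjusted p = 2.17e-07, but adjusted p = 0.064 with an estimated correlation), among them Birc5 (-6.59 ± 0.74), Aurkb (-5.30 ± 0.78) and Mki67 (-5.16 ± 0.55). Of 10 Notch pathway genes 7 were lower and 1, Lfng, higher (8 and 1 over the list alone, adjusted p = 0.00437). The call of Lfng was lost without any 1 of brush 2 to 5 or EpCAM+ 1, 3, 4, 6 or 7 (adjusted p = 0.0586 to 0.0835). The Notch target Hes1 (-5.68 ± 0.86) and the receptor Notch1 (-5.19 ± 0.51) were lower. Of 14 genes induced by tissue dissociation 13 were lower (14 over the list alone, adjusted p = 1.23e-07, but adjusted p = 0.0537 with an estimated correlation), including the phosphatase Dusp1 (-4.57 ± 0.51) and Fos (-3.04 ± 0.34).

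**Figure D2:**
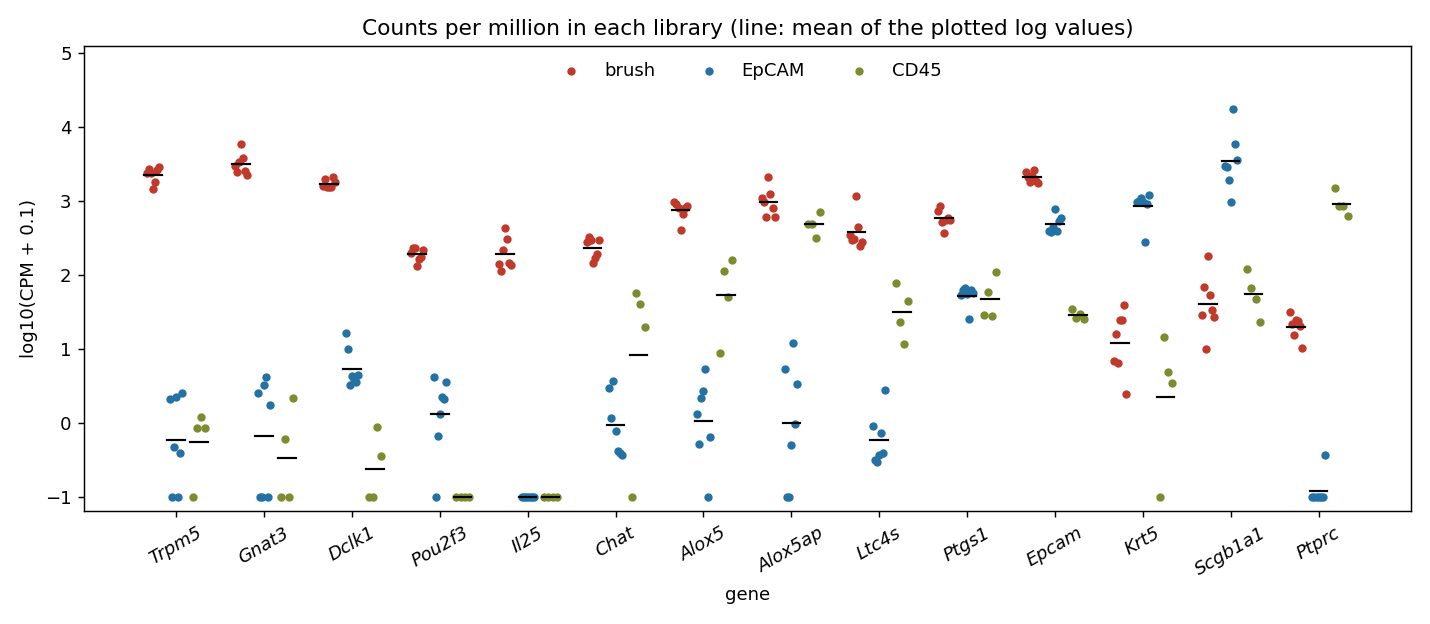
Each point is the log10(CPM + 0.1) of 1 gene in 1 library, for 14 genes in brush (n = 7), EpCAM+ (n = 7) and CD45+ cells (n = 4), and lines are means of the plotted values. Trpm5 and Gnat3 average 2330 and 3350 CPM in brush cells and below 2 CPM in both other groups, whereas Alox5ap averages 1070 CPM in brush cells and 503 CPM in CD45+ cells.

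Enzymes that make leukotrienes and prostaglandins differed in both directions between brush and EpCAM+ cells. Alox5, which encodes 5-lipoxygenase, averaged 776 ± 188 CPM in brush cells and 1.72 ± 1.80 CPM in EpCAM+ cells (log2 fold change 8.79 ± 0.71), and its partner Alox5ap 1070 ± 530 and 3.06 ± 4.29 CPM (8.54 ± 0.87). Ltc4s, the synthase of leukotriene C4, averaged 441 ± 330 against 0.724 ± 0.899 CPM (9.30 ± 0.69). The EpCAM+ means of Alox5 and Alox5ap were 1.13 and 1.62 CPM without replicate 5, and that of Ltc4s was 0.397 CPM without replicate 7. Ptgs1, cyclooxygenase 1, averaged 599 ± 159 against 54.2 ± 13.5 CPM (3.47 ± 0.34) and Hpgds, the hematopoietic prostaglandin D synthase, 57.5 ± 16.3 against 9.25 ± 5.73 CPM (2.65 ± 0.37). Alox15, another lipoxygenase, was lower (-6.71 ± 0.96). In all, 7 of 24 synthesis genes were higher and 9 lower (7 and 13 adjusted over the list alone, adjusted p = 0.677). Of 7 eicosanoid receptors tested 1 was higher and 3 lower (1 and 3 over the list alone, adjusted p = 0.728): Ptger1 was higher (1.10 ± 0.29), Ptger4 lower (-3.84 ± 0.74), and the EpCAM+ to brush ratio was 14.6 (3.7 to 126) for Cysltr1, a cysteinyl leukotriene receptor, and 11.7 (2.9 to 102) for Ltb4r1. With voom the calls of Cysltr1 (-1.57, adjusted p = 0.0776) and Ltb4r1 (-1.42, adjusted p = 0.0849) were lost. Cysltr2 and Oxgr1, the other cysteinyl leukotriene receptors, had too few counts for the test, with 15 and 1 counts over the 7 brush libraries.

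Genes of cholinergic, purinergic and cytokine signalling also differed in both directions. Of 7 cholinergic genes 4 were higher and 1 lower (4 and 1 over the list alone, adjusted p = 0.184): Chat, Slc44a2 and Slc44a4, which carries choline (2.52 ± 0.40), and Slc18a3, the vesicular acetylcholine transporter (ratio 155, 27.4 to 6170), were higher, and the muscarinic receptor Chrm3 was lower (-3.65 ± 0.86). Chat drives the reporter, and Slc18a3, with 151 counts in brush cells, lies within the bounds of Chat, so it may not be independent of the sort either. Of 13 purinergic and adenosine receptors 5 were higher and 3 lower (5 and 3 over the list alone, adjusted p = 0.487), with Adora1 (5.96 ± 0.65) and P2rx1 (4.93 ± 0.91) higher and P2ry1 lower (-5.22 ± 0.62), but 2 were higher with only these 2 groups fitted. Of 21 epithelial cytokines 3 were higher and 12 lower (4 and 12 over the list alone, adjusted p = 0.0481, but adjusted p = 0.479 with an estimated correlation). Il25, Il18 and Csf2 were the higher ones, and the chemokine Cxcl17 was lower (-6.72 ± 0.64). Csf2 was at a low level, with 11 counts over the brush libraries and 1 in EpCAM+ cells (ratio 11.3, 1.64 to 487). Of 16 type 2 cytokine receptors and targets 3 were higher and 7 lower (3 and 7 over the list alone, adjusted p = 0.977). Il17rb, Il4ra and Il13ra1 were higher, the last a subunit of the IL-13 receptor at 369 ± 123 against 179 ± 83 CPM (1.05 ± 0.41, adjusted p = 0.0455), and Fcgbp, which encodes a mucus protein, was lower (-4.04 ± 0.52), as was the chitinase-like gene Chil4 (ratio 843, 151 to 33300). With only these 2 groups fitted, 3 type 2 genes were lower. The call of Il13ra1 was lost without any 1 of 11 libraries (brush 1, 2, 5, 6 or 7, EpCAM+ 3, 4, 5, 6 or 7, or CD45+ 3), at adjusted p = 0.0521 to 0.095.

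Brush cells also held transcripts of genes best known from leukocytes. The adaptor Fyb (10.97 ± 0.55), the exchange factor Vav1 (10.38 ± 0.64) and the GTPase Rac2 (8.91 ± 0.63) were higher than in EpCAM+ cells. Ptprc, which encodes CD45, averaged 21.0 ± 6.82 CPM in brush cells, 0.0385 ± 0.102 CPM in EpCAM+ cells (ratio 589, 105 to 23300) and 962 ± 368 CPM in CD45+ cells. The EpCAM+ level of Ptprc rested on 1 count, in replicate 7. Of 22 pan-leukocyte genes 14 were higher and 3 lower (15 and 4 over the list alone, adjusted p = 0.000203, but adjusted p = 0.107 with an estimated correlation), Arhgdib with the largest decrease (-4.13 ± 0.47). The fit of only these 2 groups, which tests fewer genes, left 6 pan-leukocyte genes higher. Of 23 genes that signal directly below immune receptors 15 were higher and 2 lower (16 and 2 over the list alone, adjusted p = 8.19e-13), among them Cd300lf, Sh2d6 and the kinase adaptor Pik3r5 (10.93 ± 0.74), with Lat2 lower (-2.73 ± 0.50).

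Markers of single leukocyte classes and of other tissues did not pass the list test. Macrophage and dendritic cell genes were higher for 7 and lower for 5 of 22 (8 and 5 over the list alone, adjusted p = 0.728), with the complement gene C1qa at least 24.3-fold higher, at a low level, and Lyz2 lower (-6.42 ± 0.53). Without brush replicates 1, 2, 3 or 7 taken 1 at a time, 3 of these genes were lower. With only these 2 groups fitted 2 were higher and 3 lower. Of 13 MHC class II genes 2 were higher and 1 lower (2 and 1 over the list alone, adjusted p = 0.968). H2-Oa (at least 9.25-fold) and Cd40 were the higher ones, and Cd80 was lower (-3.28 ± 0.78). The call of H2-Oa was lost without brush replicate 7 (adjusted p = 0.32), with DESeq2 (0.114) and with voom (0.304). That of Cd40 was lost without brush 1 (0.528) or EpCAM+ 2, 3, 4 or 7 (0.0553 to 0.0723), with DESeq2 (0.147), with voom (0.307) and without the 3 libraries that stood apart (0.0569). Of 12 B cell genes Cd79b, a B cell receptor subunit, was higher (4.98 ± 0.46, 1 over the list alone, adjusted p = 0.589). Of 16 T, NK and innate lymphoid cell genes 4 were lower (4 over the list alone, adjusted p = 0.725): Gata3, Cd5, Gzma and Cd247, the last not without brush 1, 3, 6 or 7 or EpCAM+ 6 or 7 (adjusted p = 0.0518 to 0.0724). Voom ended the calls of Gzma (adjusted p = 0.0826) and Cd247 (0.0686). Of 9 mast cell and granulocyte genes Kit, a growth factor receptor (2.98 ± 0.30), and Siglecf (at least 14.7-fold) were higher and Hdc, histidine decarboxylase, was lower (-2.88 ± 0.63), with 2 and 1 over the list alone (adjusted p = 0.589).

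For cells outside the gates, the endothelial genes Tek (8.16 ± 0.60) and Esam (3.11 ± 0.57) were higher of 4 tested (2 over the list alone, adjusted p = 0.132). The fibroblast genes Dcn (-6.16 ± 0.56) and Fn1 (-4.72 ± 0.74) were lower and Pdgfra higher (ratio 103, 28.1 to 855) of 3 tested (2 and 1 over the list alone, adjusted p = 0.451). Of 3 Schwann cell and neuron genes tested Mbp (-0.92 ± 0.27) and Ncmap (-3.08 ± 0.78) were lower (2 over the list alone, adjusted p = 0.509). Hemoglobin genes Hbb-b1 and Hbb-bs were lower of 4 red blood cell genes (3 over the list alone, adjusted p = 0.728). Leaving out any 1 of brush 1 to 6 or CD45+ 4 ended the call of Hbb-b1 (0.0515 to 0.0816), and any 1 of brush 1, 3, 4, 5 or 6 or EpCAM+ 2, 5 or 6 that of Hbb-bs (0.0609 to 0.0972). Both calls were also lost with DESeq2 (0.0557 and 0.0913), voom (0.261 and 0.439), no filter (0.0507 and 0.0907) and without the 3 libraries that stood apart (0.108 and 0.144). RSEM counts ended that of Hbb-bs (0.138). The lists of 8 mitochondrially encoded genes and 6 sex-linked genes did not pass the camera test (adjusted p = 0.915 and 0.968).

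Over all 13418 genes, 2458 were higher and 2949 lower in brush than in EpCAM+ cells (40.3% of those tested), of which 2111 and 2635 differed at least 2-fold. With an estimated correlation, 7 of the 12 lists past the camera test still passed: brush markers, taste transduction, basal, club and goblet, ionocyte, Notch and immune receptor signalling genes. The EpCAM+ gate as labelled could include brush cells, and the 23 brush markers other than Chat with at least 100 CPM in brush cells had a median EpCAM+ level of 0.194% of the brush level (highest 9.7%).

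The comparison with CD45+ cells asked which brush cell genes also differ from those of tracheal hematopoietic cells. Trpm5 averaged 0.651 ± 0.463 CPM and Gnat3 0.633 ± 0.962 CPM in CD45+ cells (SD, n = 4), log2 fold changes of 11.36 ± 0.93 (SE, adjusted p = 9.29e-10) and 12.18 ± 1.28 (adjusted p = 4.17e-08) in favour of brush cells. Pou2f3 and Il25 had 0 counts in CD45+ cells and were at least 1200-fold and 929-fold higher in brush cells. Dclk1 averaged 0.255 ± 0.361 CPM (11.97 ± 0.82), Avil 0.416 ± 0.287 CPM (11.16 ± 0.68), Gfi1b 0.939 ± 0.663 CPM (3.59 ± 0.59) and Il17rb 9.46 ± 8.09 CPM in CD45+ cells (3.85 ± 0.56). Without CD45+ replicate 3 the CD45+ means of Dclk1 and Il17rb were 0.0833 and 5.93 CPM, and without replicate 4 that of Gnat3 was 0.167 CPM. Chat averaged 28.9 ± 24.4 CPM in CD45+ cells (2.97 ± 0.62, adjusted p = 0.000395), and the gate genes Epcam 28.9 ± 4.25 CPM (6.22 ± 0.42) and Ptprc 962 ± 368 CPM (-5.53 ± 0.39).

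By the same rule of level and overlap, the largest increases over CD45+ cells, besides Pou2f3, Il25 and Gnat3, were of genes of several kinds. Sox9, a transcription factor, was at least 1860-fold higher, Ms4a15, a membrane protein, at least 1210-fold, Sucnr1 at least 1170-fold, Ovol3, a zinc finger protein, at least 1140-fold and Ly6g6f at least 528-fold. The adaptor Sh2d7 and the bitter taste receptor Tas2r108 had brush to CD45+ ratios of 11900 (2140 to 470000) and 7570 (1360 to 299000). Of 30 brush cell markers 29 were higher (29 over the list alone, adjusted p = 5e-19), again not as independent evidence, and all 18 taste transduction genes were (18 over the list alone, adjusted p = 1.23e-11). As against EpCAM+ cells, the count and p of the taste list were set in part by the filter on low counts. Of 20 pan-epithelial genes 17 were higher (17 over the list alone, adjusted p = 8.43e-13), led by the tight junction gene Cldn7 (8.65 ± 0.62), Rab25 (8.59 ± 0.86) and Krt18 (8.56 ± 0.64).

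Several leukotriene and prostaglandin genes were also present in CD45+ cells. Alox5 averaged 82.8 ± 67.1 CPM there (3.19 ± 0.67), Ltc4s 39.3 ± 29 CPM (3.58 ± 0.65) and Ptgs1 55.9 ± 37.9 CPM (3.39 ± 0.43), all lower than in brush cells. Alox5ap at 503 ± 164 CPM (1.09 ± 0.75, adjusted p = 0.25) and Hpgds at 53.3 ± 34.1 CPM (0.13 ± 0.41, adjusted p = 0.825) did not pass the test, although the fit of only these 2 groups called Alox5ap (1.08, adjusted p = 0.0387). Of 24 synthesis genes 6 were higher and 11 lower (6 and 11 over the list alone, adjusted p = 0.471), with the thromboxane synthase Tbxas1 lower (-8.24 ± 0.64). Of 7 eicosanoid receptors 6 were lower (6 over the list alone, adjusted p = 6.91e-06). The CD45+ to brush ratio was 835 (230 to 6900) for Cysltr1, which averaged 58.9 ± 39.7 CPM in CD45+ cells, and 1680 (465 to 13900) for Ltb4r1, a leukotriene B4 receptor. Cysltr2 had 37 counts and Oxgr1 2 counts in the 4 CD45+ libraries.

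Genes of leukocytes were lower in brush cells. Il1b, which encodes IL-1 beta, Cd209a, a dendritic cell lectin, and Cybb, the phagocyte oxidase, had 0 counts in brush cells and were at least 18700-fold, 7340-fold and 5410-fold higher in CD45+ cells. The B cell genes Ms4a1 and Cd79a and the chemokine Ccl3 were at least 3700-fold, 3390-fold and 1370-fold higher there, and the CD45+ to brush ratios were 31800 (5710 to 1260000) for Ccl6, 17400 (4800 to 143000) for Retnla, 8120 (1460 to 321000) for Ccl4 and 5740 (1590 to 47400) for Cd52. All 22 macrophage and dendritic cell genes (22 over the list alone, adjusted p = 7.89e-18), all 13 MHC class II genes (13, adjusted p = 4.76e-13), all 12 B cell genes (12, adjusted p = 5.5e-12) and 15 of 16 T, NK and innate lymphoid genes (15, adjusted p = 3.48e-10, but adjusted p = 0.0749 with an estimated correlation) were lower. Of 9 mast cell and granulocyte genes 8 were lower (8 over the list alone, adjusted p = 6.91e-06) and Kit was higher (2.17 ± 0.36). With no filter on low counts, 14 mast cell and granulocyte genes were lower.

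Pan-leukocyte and immune signalling genes again divided. Of 22 pan-leukocyte genes 19 were lower (19 over the list alone, adjusted p = 1.86e-13), and Vav1 (1.85 ± 0.51), Fyb (1.61 ± 0.42) and the phosphatase Ptpn6 were higher in brush than in CD45+ cells. Of 23 immune receptor signalling genes 11 were higher and 10 lower (11 and 10 over the list alone, adjusted p = 0.626), with Sh2d6 (9.45 ± 0.69), Bmx (8.18 ± 0.67) and Cd300lf (3.51 ± 0.38) higher and Themis2 lower (-8.88 ± 0.61).

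Several other lists had more genes lower than higher in brush cells against CD45+ cells. All 14 proliferation genes were lower in brush cells (14 over the list alone, adjusted p = 3.48e-07, but adjusted p = 0.0655 with an estimated correlation), among them Aurkb (-6.54 ± 0.82) and Mki67 (-6.36 ± 0.59). Dissociation stress genes were lower for 8 of 14 (8 over the list alone, adjusted p = 0.0196, but adjusted p = 0.403 with an estimated correlation), with Dusp1 at -4.58 ± 0.53. Purinergic receptors were lower for 9 and higher for 3 of 13 (9 and 3 over the list alone, adjusted p = 0.049, but adjusted p = 0.348 with an estimated correlation): Adora1 (5.06 ± 0.82), P2rx6 (at least 76.0-fold) and P2ry2 were higher and P2ry6 was lower (-5.13 ± 0.54). Epithelial cytokines were lower for 10 and higher for 3 of 21 (11 and 3 over the list alone, adjusted p = 0.0173, but adjusted p = 0.348 with an estimated correlation), with Il25, Il34 and Vegfa higher and Cxcl2 lower (-9.20 ± 0.89). Type 2 genes were lower for 9 and higher for 3 of 16 (9 and 3 over the list alone, adjusted p = 0.00869, but adjusted p = 0.101 with an estimated correlation): Il17rb, Clca1 and Il13ra1 (2.32 ± 0.53, with 71.9 ± 50.2 CPM in CD45+ cells) were higher.

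The remaining epithelial lists did not pass the camera test against CD45+ cells. Basal genes were higher for 7 and lower for 1 of 19 (7 and 1 over the list alone, adjusted p = 0.238), with Itgb4 higher (5.01 ± 0.46) and Icam1 lower (-4.61 ± 0.61), and Krt5 averaged 5.58 ± 6.09 CPM in CD45+ cells (1.34 ± 0.66, adjusted p = 0.104). Krt5 passed with DESeq2 (adjusted p = 0.0414), without brush replicate 7 (1.57) and without CD45+ replicate 2 (2.18), where its CD45+ mean was 2.71 CPM. Ciliated genes were higher for 7 and lower for 2 of 23 (6 and 2 over the list alone, adjusted p = 0.314), with Ccdc39 at least 56.7-fold higher and Rfx2 lower (-1.61 ± 0.42). Without CD45+ replicate 3, with voom or with only these 2 groups fitted, 4 ciliated genes were higher, and 3 with a minimum of 10 CPM. Foxj1 averaged 0.0635 ± 0.127 CPM in CD45+ cells, from 1 count in replicate 4. Club and goblet genes Spdef (at least 458-fold) and Aldh1a1 (2.33 ± 0.45) were higher of 18 and Tff2 lower (2 and 0 over the list alone, adjusted p = 0.471), while Scgb1a1 averaged 64.7 ± 41.4 CPM in CD45+ cells (-0.18 ± 0.72, adjusted p = 0.868). The call of Tff2 was lost without any 1 of 9 libraries (brush 1 or 3 to 7, EpCAM+ 5, or CD45+ 1 or 2), at adjusted p = 0.0598 to 0.302. It was also lost with RLE (0.0534) or upper-quartile scaling (0.0576), RSEM counts (0.11), voom (0.181), a minimum of 10 CPM (0.0517), no filter (0.107) or without the 3 libraries that stood apart (0.184). Of 12 neuroendocrine genes 5 were higher (6 over the list alone, adjusted p = 0.238), among them Resp18 (at least 38.3-fold), Scg5 (4.73 ± 0.81), Calca and Chgb. The count was 3 without CD45+ replicate 3 or 4 or with a minimum of 10 CPM and 2 with voom. The call of Calca was lost without CD45+ 2, 3 or 4 (adjusted p = 0.0518 to 0.0743), with voom (0.689), with no filter (0.0797) and without the 3 libraries that stood apart (0.053). Voom also ended the call of Resp18 (0.0688). The ionocyte gene Atp6v1c2 was higher (2.11 ± 0.60) and Stap1 (-7.52 ± 0.78) and Atp6v0d2 lower of 6 (1 and 2 over the list alone, adjusted p = 0.267).

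Among the small lists, the cholinergic genes Chat and Slc44a4 (ratio 1920, 658 to 9330) were higher of 7 (2 over the list alone, adjusted p = 0.255). The Notch ligands Jag2 (3.40 ± 0.49) and Dll1 (3.29 ± 0.77) were higher and the receptors Notch1 (-5.02 ± 0.54) and Notch2 (-3 ± 0.30) lower of 10 (2 and 2 over the list alone, adjusted p = 0.471). Pdgfra (4.91 ± 0.88) was higher and Fn1 lower (-9.55 ± 0.85) of 3 fibroblast genes (adjusted p = 0.474), and Tek and Esam (3.09 ± 0.74) were higher and Pecam1 lower of 4 endothelial genes (adjusted p = 0.73), with equal counts over each list alone. Ncmap, a Schwann cell gene, was lower (-2.59 ± 0.90) of 3 tested (2 over the list alone, with no pass in the camera test), but not without CD45+ 1 or 3 (0.0508 and 0.152), with RSEM counts (0.0785), with voom (0.645) or without the 3 libraries that stood apart (0.0629).

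**Figure D3:**
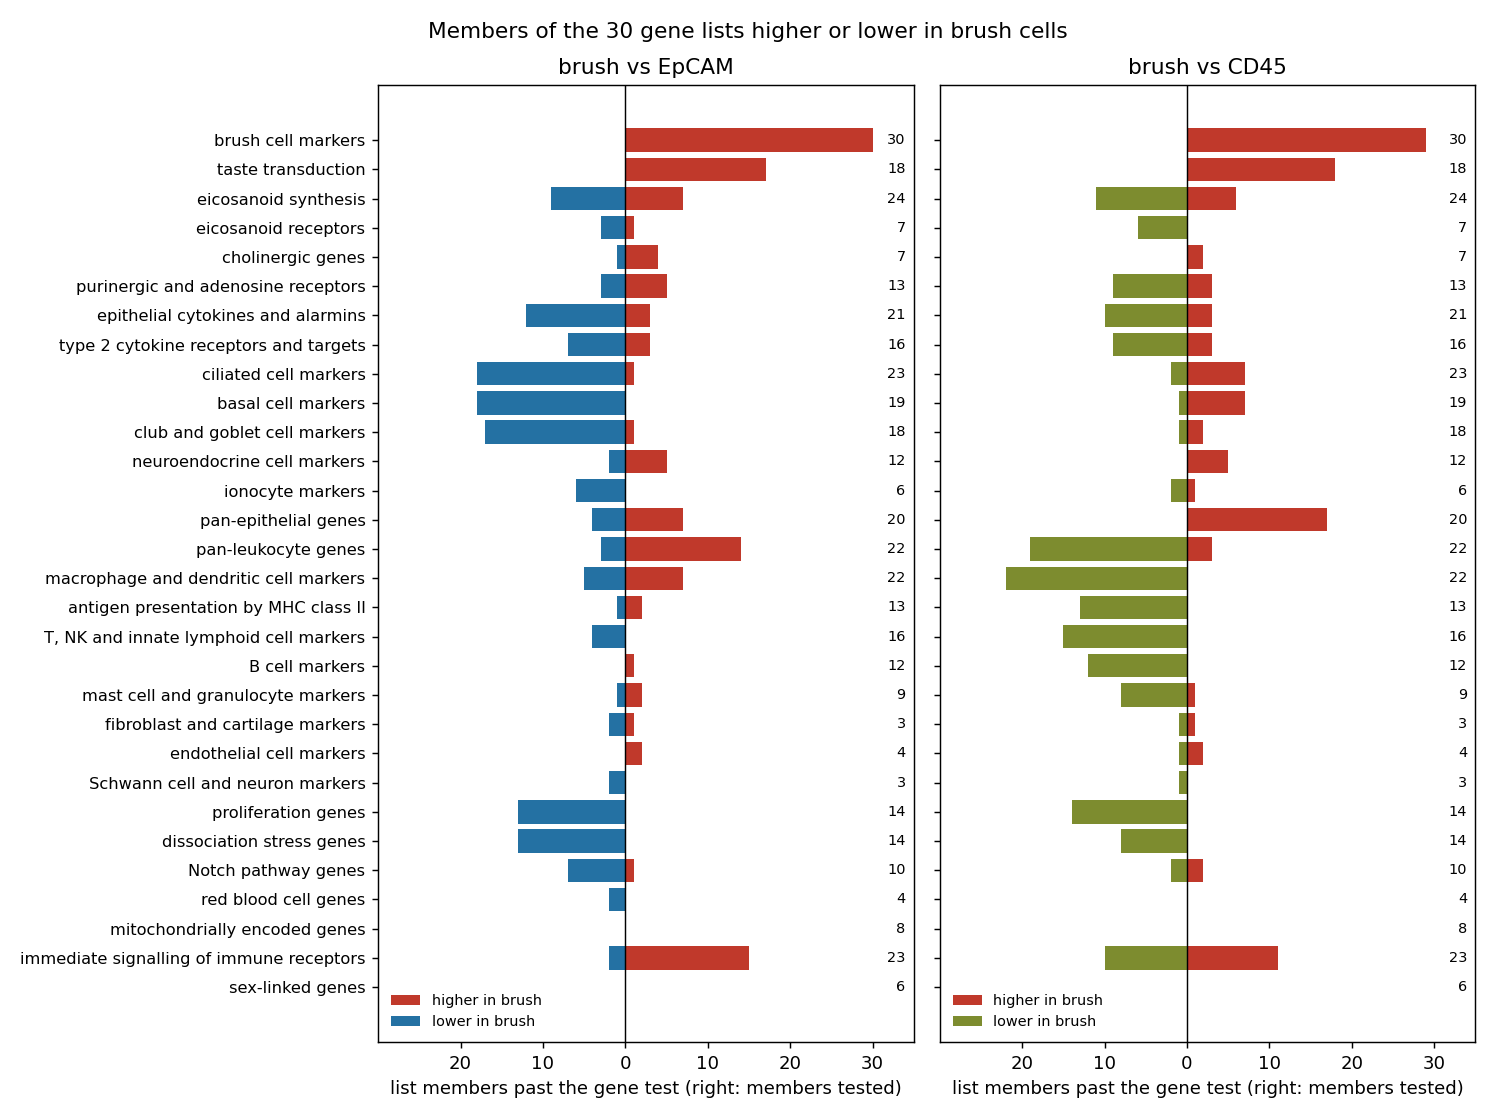
Bars give, for each list, the number of tested members higher and lower in brush cells than in EpCAM+ cells and than in CD45+ cells at an edgeR adjusted p below 0.05. All 30 brush markers are higher than in EpCAM+ cells and 29 than in CD45+ cells, and all 22 macrophage and dendritic cell genes are lower than in CD45+ cells.

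In total 3133 genes were higher and 3005 lower in brush than in CD45+ cells (45.7% of 13418), of which 3003 and 2797 differed at least 2-fold. With an estimated correlation, 9 of the 15 lists past the camera test still passed: brush markers, taste transduction, eicosanoid receptors, pan-epithelial, pan-leukocyte, macrophage and dendritic cell, MHC class II, B cell, and mast cell and granulocyte genes. Only 4 libraries represented CD45+ cells, and 1 of them (replicate 1) held 371652 counts.

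The signature of brush cells was taken as the genes at least 2-fold higher than in both other populations. Ranked by the smaller of the 2 changes, its first 20 genes with at least 50 CPM included chemosensory genes (Trpm5, Gnat3, Gnb3, Tas2r138, Tas2r108 and the olfactory receptor Olfr461), the receptors and membrane proteins Sucnr1, Pcdh20, Ms4a15 and Ly6g6f, and the cytokine Il25. They also included the regulators Ovol3 and Hmx3, the adaptors Sh2d6 and Sh2d7, the G protein regulator Rgs13, the cytoskeletal genes Avil and Nefl, and the sialyltransferase St6gal2. Against EpCAM+ cells, Rgs13 had a log2 fold change of 10.37 ± 0.82, Hmx3 of 9.22 ± 0.59 and Ly6g6f of 8.81 ± 0.66, and Olfr461 had a ratio of 2910 (522 to 115000). Against CD45+ cells, Rgs13 had a log2 fold change of 8.75 ± 1.00 and Gnb3 of 11.85 ± 1.15, Hmx3 was at least 492-fold higher, and Nefl, a neurofilament subunit, had a ratio of 1340 (240 to 52900).

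On GRCm38, the 3 chemosensory receptor genes Tas2r108 (chromosome 6, 40493529 to 40494541, plus strand), Olfr461 (40542171 to 40555050, minus strand) and Tas2r138 (40612315 to 40613310, minus strand) are neighbours on chromosome 6. Trpm5 lies on chromosome 7 (143069153 to 143094642, minus strand), Gnat3 on chromosome 5 (17962549 to 18019834, plus strand), Pou2f3 on chromosome 9 (43123939 to 43210369, minus strand) and Sucnr1 on chromosome 3 (60081869 to 60087566, plus strand). Chat (32408203 to 32465989, minus strand), Il25 (54932695 to 54935837, plus strand) and Pcdh20 (88464743 to 88471396, minus strand) lie on chromosome 14. Slc18a3 (32462438 to 32464850, minus strand) lies within the bounds of Chat on the same strand, so how reads were divided between them is uncertain.

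The signature held 1340 genes, and 1179 genes were at least 2-fold lower in brush cells than in both other populations. Independent lists of the same sizes would share 472 and 549 genes. Both contrasts use the same brush libraries, and 20 simulations of unchanged groups gave a median and a highest signature of 0 genes. With no gene changed, hardly any pass an adjusted p, so this 0 does not measure what shared libraries add to the overlap. In those simulations a median of 38 genes was shared at unadjusted p below 0.05 in the upward direction, from medians of 282 and 333. The log2 fold changes of the 2 contrasts had a median correlation of 0.412 there, so shared libraries alone link the contrasts. Neither 472 nor 549 allows for that link. With the brush libraries divided between the contrasts, 4 against EpCAM+ and 3 against CD45+ cells, 1053 genes were shared (305 for independent lists), and 1058 (324) with 3 and 4. Of the signature, 834 genes were among the 12466 that pass the filter on low counts without the brush libraries. The rest passed only through brush libraries, which favours genes high in both contrasts. The upward expectations of 472, 305 and 324 do not allow for this, so the excess over them was set in part by the filter. Another 186 genes were higher than in EpCAM+ and lower than in CD45+ cells, and 338 the reverse.

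**Figure D4:**
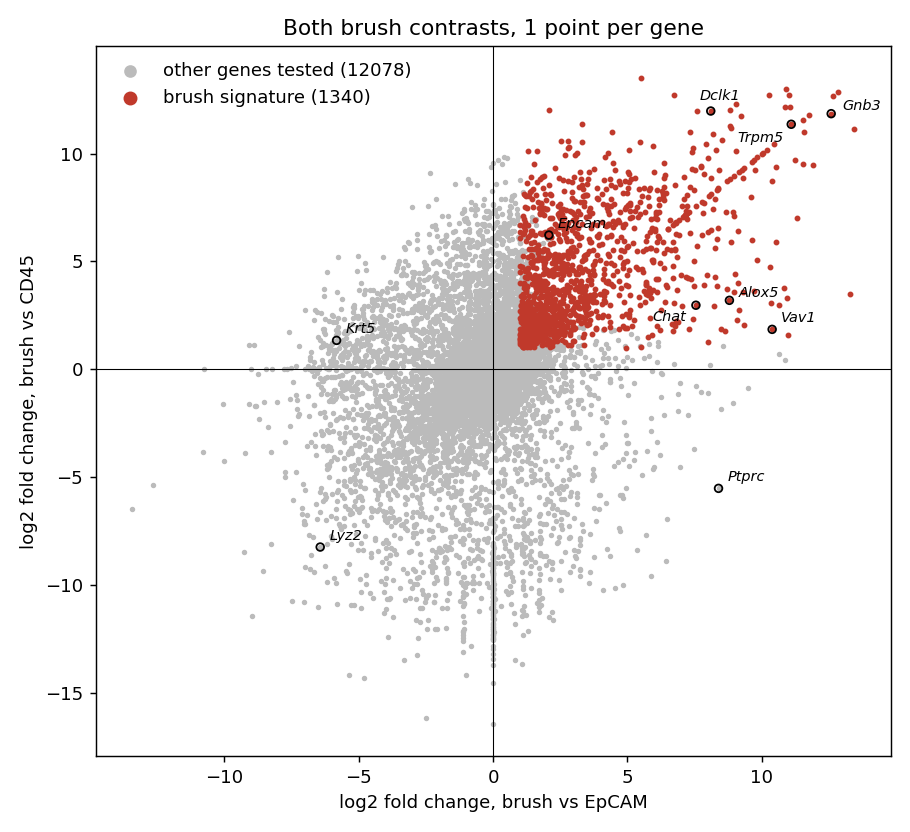
Each point is 1 of 13418 genes, placed by its fitted log2 fold change in brush against EpCAM+ cells and in brush against CD45+ cells, with the 1340 signature genes coloured. Trpm5 (11.09 and 11.36) and Dclk1 (8.10 and 11.97) lie far up in both directions, and Krt5 (-5.82) and Lyz2 (-6.42) are among the genes lower than in EpCAM+ cells.

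EpCAM+ and CD45+ cells were compared as the reference pair. EpCAM+ cells held far more of the epithelial genes: Lurap1l and Rnf186, a ubiquitin ligase, had 0 counts in CD45+ cells and were at least 504-fold and 313-fold higher (n = 7 and 4), and Upk3bl, a uroplakin-like gene, had a log2 fold change of 9.58 ± 1.15 (SE, adjusted p = 3.55e-07). The EpCAM+ to CD45+ ratios of Aldh1a7, an aldehyde dehydrogenase, and Eppk1, epiplakin, were 2330 (418 to 92100) and 1520 (273 to 60100). In the other direction, the complement genes C1qb and C1qa, the tetraspanin Cd53, the adaptor Tyrobp and the chemokine Ccl4 had 0 counts in EpCAM+ cells and were at least 11400-fold, 10300-fold, 8300-fold, 5630-fold and 2780-fold higher in CD45+ cells. Ptprc had a CD45+ to EpCAM+ ratio of 25000 (4490 to 988000) and Epcam a log2 fold change of 4.14 ± 0.38, both being genes of the gates.

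By list, all 20 pan-epithelial genes (20 adjusted over the list alone, camera adjusted p = 3.86e-16), all 18 club and goblet genes (18, adjusted p = 7.29e-12), 18 of 19 basal genes (18, adjusted p = 2.33e-12) and 20 of 23 ciliated genes (20, adjusted p = 3.44e-06, but adjusted p = 0.102 with an estimated correlation) were higher in EpCAM+ cells. Examples were Rab25 (8.49 ± 0.85), Krt13 (8.53 ± 1.19), Krt5 (7.15 ± 0.85) and Scgb1a1 (6.36 ± 0.98). All 22 pan-leukocyte genes (22 over the list alone, adjusted p = 4.16e-25), 22 macrophage and dendritic cell genes (22, adjusted p = 3.44e-18), 13 MHC class II genes (13, adjusted p = 1.1e-14) and 12 B cell genes (12, adjusted p = 8.27e-14) were lower, among them H2-Eb1 (-11.29 ± 1.03) and Ighm (-14.29 ± 0.99). So were 14 of 16 T, NK and innate lymphoid genes (15 over the list alone, adjusted p = 2.3e-10, but adjusted p = 0.067 with an estimated correlation), 8 of 9 mast cell and granulocyte genes (9, adjusted p = 1.83e-08), and 20 of 23 immune signalling genes (20, adjusted p = 1.1e-14). In that last list Bmx was higher (3.35 ± 0.55). A minimum of 10 CPM left 6 ciliated genes higher, and with no filter 14 mast cell and granulocyte genes were lower.

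Between EpCAM+ and CD45+ cells some of the remaining lists differed in 1 direction and others in both. All 7 eicosanoid receptors (7 over the list alone, adjusted p = 1.23e-06) were lower, with Cysltr1 at 0.938 ± 0.644 CPM in EpCAM+ cells (-5.92 ± 0.53), as were 11 of 16 type 2 genes with 4 higher (11 and 4, adjusted p = 0.000505) and 7 of 13 purinergic receptors with 3 higher (8 and 3, adjusted p = 0.0201, but adjusted p = 0.235 with an estimated correlation). Il13ra1 was higher in EpCAM+ cells (1.27 ± 0.50, adjusted p = 0.0477), a call lost without any 1 of brush 3 or 5, EpCAM+ 1, 2, 3 or 6, or CD45+ 1, 3 or 4 (0.0514 to 0.101), with RSEM counts (0.0667) and with only these 2 groups fitted (0.0814). Dissociation stress genes were higher for 6 of 14 (6 over the list alone, adjusted p = 0.0254, but adjusted p = 0.43 with an estimated correlation), including Ier2 (2.43 ± 0.51) and Egr1 (2.11 ± 0.38). Brush markers, with 7 higher and 11 lower of 30 (7 and 12 over the list alone, adjusted p = 0.0758), and taste genes, with 2 higher and 1 lower of 18 (1 and 1 over the list alone, adjusted p = 0.586), did not pass the list test. The taste genes were Trpm4 (1.97 ± 0.49), Plcb2 (-7.28 ± 0.60) and Gng13, whose call was lost without EpCAM+ 2 or CD45+ 2, 3 or 4 (0.0519 to 0.135), with voom (0.426), with no filter (0.0537) and without the 3 libraries that stood apart (0.0509). Eicosanoid synthesis genes were higher for 4 and lower for 8 of 24 (4 and 8 over the list alone, adjusted p = 0.374), with Ptges higher (5.79 ± 0.54) and Alox5ap lower (-7.45 ± 0.85). The ionocyte list had 4 higher and 2 lower of 6 (4 and 2 over the list alone, adjusted p = 0.374), Notch genes 4 higher and 2 lower of 10 (5 and 2, adjusted p = 0.192) and cytokines 8 higher and 9 lower of 21 (8 and 10, adjusted p = 0.355).

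Among 14 proliferation genes Mcm5 (-1.73 ± 0.47), Mcm2 (-1.30 ± 0.41), Mki67 and Top2a were lower in EpCAM+ cells (2 over the list alone, adjusted p = 0.263). The calls of Mcm2, Mki67 and Top2a were lost without CD45+ 2 (adjusted p = 0.0595, 0.279 and 0.523), and each was also lost without other single libraries. RLE or upper-quartile scaling, DESeq2, RSEM counts, no filter and leaving out the ribosomal RNA genes also ended the calls of Mki67 (0.0522 to 0.0764) and Top2a (0.0557 to 0.0677). The fit of only these 2 groups ended that of Top2a (0.116). Chat (-4.58 ± 0.61) and Slc18a3 (ratio 80.3, 13.7 to 3240) were lower and Slc44a4 (ratio 301, 103 to 1460) and Chrm3 higher of 7 cholinergic genes (2 and 2 over the list alone, adjusted p = 0.971). The call of Chrm3 was lost without CD45+ 2 or 3 (0.0948 and 0.109). Of 12 neuroendocrine genes 2 were higher (2 over the list alone, adjusted p = 0.374), among them Chga (6.91 ± 1.68), a call lost with voom (4.82, adjusted p = 0.176). Voom also ended the call of Slc18a3 (-2.86, adjusted p = 0.0723). Dcn was higher (5.01 ± 0.68) and Fn1 lower (-4.83 ± 0.66) of 3 fibroblast genes (adjusted p = 0.899), and Pecam1 was lower (-7.91 ± 0.67) of 4 endothelial genes (adjusted p = 0.355), with equal counts over each list alone.

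In this pair 3007 genes were higher and 2423 lower in EpCAM+ cells (40.5% of 13418), of which 2906 and 2235 differed at least 2-fold. With an estimated correlation, 11 of the 15 lists past the camera test still passed. Of the sex-linked genes Tsix was higher in EpCAM+ cells (2.73 ± 1.02, adjusted p = 0.0359, 0 over the list alone), and with RSEM counts its change was -0.30 (adjusted p = 0.912). Without EpCAM+ 5 or CD45+ 2 or 3 the call of Tsix was lost (0.0805 to 0.13). It was also lost with only these 2 groups fitted (0.0509) and without the 3 libraries that stood apart (0.0626). Xist was at 0 and 0.3 CPM in CD45+ 2 and 3, which had 155.3 and 153 CPM of Y-linked genes. It was at 152.3 and 341.1 CPM in CD45+ 1 and 4, which had 0. In EpCAM+ cells only replicates 3 and 4 had Xist below 91.3 CPM (4.5 and 2.8) and over 0.2 CPM of Y-linked genes (109.8 and 57). Tsix overlaps Xist on the opposite strand, and the strand used for counting is not given.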

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

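The tests of fewer counts, of transcript length and of brush cells among CD45+ cells were chosen after the result was seen, the libraries that stood apart were themselves picked from the data, and the other tests in this part were planned before their results were seen. A first pass took a library's distance from its group for all genes under the naming rule and marked 154 of 627 groups (24.6%). The scope was then narrowed, after that pass, to the levels printed here, where 14 of 68 groups (20.6%) held a library far from the others by Dixon's criterion, and chance alone marks about 1 in 20 groups.

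In brush cells, replicate 4 lay far above the next library for Alox5ap (2147.35 against 1250.82 CPM), Gnat3 (5965.08 against 3823.22 CPM), Ltc4s (1176.42 against 442.52 CPM) and Scgb1a1 (180.99 against 68.3 CPM). In EpCAM+ cells, replicate 5 lay above the others for Scgb1a1 (17853.04 against 5899.38 CPM) and below them for Krt5 (281.98 against 916.82 CPM) and Ptgs1 (25.3 against 52.92 CPM). EpCAM+ replicate 7 was highest for Hpgds (21.57 against 9.77 CPM), Ltc4s (2.7 against 0.8 CPM) and Ptprc (0.27 CPM against 0 in the others), and CD45+ replicate 4 for Foxj1 (0.25 CPM against 0). The values of Ptprc and Foxj1 were 1 count each in a group otherwise at 0, where any count meets the criterion, so they carry no evidence of a library that differs.

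Brush 4, EpCAM+ 5 and CD45+ 1 had the lowest median correlation with their own groups, 0.849, 0.81 and 0.759, against 0.922, 0.895 and 0.921 for the next library. Fewer counts were argued against as the whole cause: brush 4 and CD45+ 1 had the fewest counts of their groups over the genes tested other than ribosomal RNA (304904 and 208526), but in 2 of these 2 groups the others thinned to that number stayed above them (0.908 to 0.937 and 0.888 to 0.896), and EpCAM+ 5 (3400548) had more such counts than 4 of the other 6. Transcript length stays open: the correlation of a library's deviation with length lay outside its group's range in 2 of 3 groups (-0.199 in brush 4 and -0.09 in CD45+ 1), while that of EpCAM+ 5 (-0.24) lay within it. Transcripts of another sorted population in the library stay open too, since the slope toward one was the highest of the group in 2 of 3 cases (0.0788 toward EpCAM+ in brush 4 and 0.0511 toward CD45+ in EpCAM+ 5), but not in CD45+ 1. The labels name no biological difference between libraries of 1 group and none was tested, although sex-linked genes differed within each group: brush 4 had 43.4 CPM of Y-linked genes and 13.2 CPM of Xist, and EpCAM+ 5 and CD45+ 1 had 0 and 91.3 or 152.3 CPM.

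The 14 pan-leukocyte genes higher in brush than in EpCAM+ cells could come from CD45+ cells in the sort, which the CD45 gate should remove, or from brush cells themselves. Abundant markers of the leukocyte classes allow a median CD45+ share of at most 0.139% of brush RNA (macrophage and dendritic cell markers). For 6 of the genes more than 10 times that share would be needed, namely Vav1 (363%), Fyb (304%), Ptpn6 (207%), Rac2 (33.4%), Lcp1 (8.89%) and Ptprc (2.18%), which argues against CD45+ cells as the source for the first 4 of these. Single markers reached shares of 2.09% (macrophage and dendritic cell) and 9.21% (B cell), close to or above what Ptprc and Lcp1 need, so for these 2 the argument rests on the class medians alone. The other 8 genes need a median of 0.205%, so for them CD45+ cells and expression in brush cells cannot be told apart, as the shares lie too close.

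Chat was counted in 3 of the 4 CD45+ libraries (0, 225, 364 and 77 counts), at 11.9% of its mean brush level. Brush cells among the CD45+ cells would bring their other transcripts, but the 23 other brush markers had a median CD45+ level of 0.116% of the brush level, which argues against that source. Of these markers 5 exceeded the ratio of Chat, among them Spib (20.8%), Plcb2 (23.4%), Itpr2 (31.6%) and Kctd12 (52.9%). Expression of Chat in CD45+ cells stays open as a hypothesis and was not tested.

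Whether any grouping of these libraries would do was checked by refitting 100 splits of the same libraries into groups of the same sizes. In each of the 4 tests only 1 split, the real one, gave as many genes. The counts were 5407 genes against a highest other of 0 for brush and EpCAM+, and 6138 against 1427 for brush and CD45+. They were 5430 against 1463 for EpCAM+ and CD45+, and 1340 against 0 for the signature. The other splits mix sorted populations that separate from each other, which widens the spread within a group and leaves few genes to call. They therefore show only that the sorted groups differ more than mixed groups do, and cannot exclude chance.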

How the results depend on the processing

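All alternatives were planned except leaving out the ribosomal RNA genes and leaving out brush 4, EpCAM+ 5 and CD45+ 1, which were chosen after the data were seen. Under alternatives, 491 of 498 values of the gene counts, set test counts and library similarity stayed within 1.5 times the reported value and 7 moved further. Of list counts of 5 or more, 1769 of 1798 values did and 29 moved, and of list counts under 5, 3175 of 3396 did and 221 moved. Of 16090 values for single named genes, 15783 kept their direction and side of the threshold, 302 lost the call, 4 gained it and 1 reversed (Tsix in EpCAM+ against CD45+, -0.3 with RSEM counts, the cause was not tested). Leaving out 1 library at a time gave 4784 to 5872 genes between brush and EpCAM+, 5684 to 6584 between brush and CD45+, 4931 to 5786 between EpCAM+ and CD45+ and 1221 to 1375 signature genes. Without the 3 libraries that stood apart the counts were 6216, 7138, 6251 and 1437. Between 63.1% (glmTreat) and 99% (ribosomal RNA genes left out) of the signature was shared with an alternative. Upper-quartile scaling shifted the median log2 fold change by 0.124 in brush against CD45+ and 0.144 in EpCAM+ against CD45+.

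The test against a 2-fold change, which asks for larger effects by construction, gave 2987 genes between brush and EpCAM+ (1279 higher, 1708 lower), 1608 lower in EpCAM+ than in CD45+ and 845 signature genes. With an estimated correlation 7 lists passed camera in brush against EpCAM+ and 9 in brush against CD45+. With no filter on low counts, which tests more genes, 14 mast cell and granulocyte genes were lower in brush than in CD45+ and 14 in EpCAM+ than in CD45+. A minimum of 10 CPM, which tests fewer genes, left 6 ciliated genes lower in brush than in EpCAM+, 3 higher in brush than in CD45+ and 6 higher in EpCAM+ than in CD45+, and 3 neuroendocrine genes higher in brush in each brush contrast. With voom 3 neuroendocrine genes were higher than in EpCAM+, 2 higher than in CD45+, and 4 ciliated genes higher than in CD45+; the cause was not tested. Fits of only the 2 groups compared, which test fewer genes, gave against EpCAM+ 2 purinergic genes higher, 3 type 2 genes lower, 10 ciliated lower, 3 neuroendocrine higher, 2 ionocyte lower, 6 pan-leukocyte higher, and 2 macrophage and dendritic cell genes higher and 3 lower, and against CD45+ 4 ciliated genes higher. Leaving out 1 library gave 3 to 6 neuroendocrine genes higher than in EpCAM+ and 3 to 6 than in CD45+, 4 to 7 ciliated genes higher than in CD45+ and 3 to 5 macrophage and dendritic cell genes lower than in EpCAM+.

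Samples share replicate numbers, and the deviations of same-numbered libraries from their groups had correlations of -0.198 to 0.263, with the own number best in 3 of 15. Between brush and EpCAM+ libraries these were -0.069 to 0.235, most of them above 0. Y-linked genes were at 146.3 CPM in brush 6 and 0 in EpCAM+ 6, and at 0 in brush 2 and 155.3 CPM in CD45+ 2. These pairs were therefore not from 1 animal, and whether other numbers mark shared animals stays open. With the replicate block 2375 genes were higher and 2656 lower in brush than in EpCAM+, 2881 and 2689 than in CD45+, 2653 and 2124 in EpCAM+ than in CD45+, and the signature held 1322. The block moved 12 list counts by over 1.5 times and left 168 within that, and 4 ciliated genes were higher in brush than in CD45+. Of the values for single named genes, 544 kept their direction and side of the threshold with the block and 16 did not pass. Those printed in the report were Cd40, Chga, Hbb-b1 and Hbb-bs in brush against EpCAM+ (adjusted p = 0.151, 0.0537, 0.165 and 0.0589), Ncmap in brush against CD45+ (0.0681), and Chga, Chrm3, Top2a and Tsix in EpCAM+ against CD45+ (0.0683, 0.143, 0.108 and 0.0711). Depth limits the detection of low genes, with floors of 0.101 CPM in brush, 0.0986 in EpCAM+ and 0.172 in CD45+ cells, where replicate 1 held 371652 counts.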

Other observations

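The tests of symbol families were chosen after the signature was seen; the split of protocadherins into clusters, a correction of the ribosomal protein pattern and the counts by filter came after their first results. Protocadherins, cell adhesion proteins, were 1 of 32 families defined by gene symbol and tested for enrichment among the 1340 signature genes (10% of genes tested, Fisher's exact test). Of 35 protocadherins 29 were in the signature, including 17 of 20 of the gamma cluster and 9 of 9 of the beta cluster. A gene silent in the other cells passes the filter on low counts only through its brush libraries, and 25 of the 35 did so, including all 9 of the beta cluster, whose count was thus set by the filter. Among the 10 protocadherins that pass without the brush libraries 6 were in the signature (adjusted p = 0.000469, against 834 of 12466 genes), but 4 of these 6 were among 5 genes of the gamma cluster, so that p rests in part on counts that are not independent. With no filter 34 of 68 protocadherins were in the signature (adjusted p = 3.85e-21). The beta cluster runs from Pcdhb1 (chromosome 18, 37264938 to 37267525) to Pcdhb22 (37517871 to 37524479) on GRCm38. Genes of the gamma cluster, from Pcdhga1 (37661793 to 37841873) to Pcdhgc5 (37819513 to 37841873), share their last exons, so counts of its single members are uncertain and are not independent of each other. RLE and upper-quartile scaling gave 28 protocadherins and 16 of the gamma cluster, and RSEM counts 27 of 37 and 13 of 21.

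All 13 bitter taste receptors tested and all 3 olfactory receptors (Olfr12, Olfr456 and Olfr461) were in the signature, but each passed the filter only through brush libraries, so these counts were set by the filter and are given without a test. With no filter, where the signature held 1454 of 22229 genes, 21 of 35 bitter taste receptors with any count were in it, above that share (adjusted p = 1.79e-15). Of 498 olfactory receptors with any count 9 were in it (adjusted p = 5.58e-06). Only 3 olfactory receptors passed the filter on low counts, so most had too few counts to be called and no depletion can be read from that p. Many of the 22229 genes likewise have few counts, which lowers the share that the p-values without the filter are set against. Over all genes tested, the other families that passed the test upward were potassium channels (13 of 32), homeobox factors (10 of 20, among them Hmx2, Hmx3, Pou2f3 and Hoxa2 to Hoxa5), adhesion G protein-coupled receptors (9 of 18), regulators of G protein signalling (8 of 16), phospholipases (8 of 25) and Eph receptors with ephrins (5 of 15). Among the genes of these families that pass without the brush libraries, 1 of 17, 3 of 12, 4 of 12, 3 of 11, 5 of 21 and 4 of 13 were in the signature, and none of these families passed the test there (adjusted p = 1, 0.133, 0.0501, 0.117, 0.0501 and 0.0501). The signature held 0 of 78 cytosolic and 0 of 78 mitochondrial ribosomal proteins (adjusted p = 0.00144 each), 16 of 307 zinc finger proteins (adjusted p = 0.00898) and 0 of 45 NADH dehydrogenase subunits (adjusted p = 0.0437), all below the share of all genes. With the narrower set of genes none of these passed (adjusted p = 0.0501, 0.0501, 0.211 and 0.194). Genes within a family can share regulation or reads, so these p-values describe this signature and are not counts of independent events.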
